A study of Sideroxydans lithotrophicus with 27 samples.

How the data were processed

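Total RNA of 27 samples of Sideroxydans lithotrophicus ES-1 was sequenced. Per the labels' protocols, RNA was taken with an RNeasy Micro kit, treated with DNase and depleted of rRNA, although the labels' molecule field reads polyA RNA, and the libraries were run on an Illumina NextSeq sequencer. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 after FastQC, aligned with Bowtie2 2.3.5.1 and counted with HTSeq. The genome build, strand setting and handling of reads that map to several places were not given in the sources used here, so reads shared by similar genes such as the cyc2 copies cannot be placed.

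The deposited table holds the authors' values in the expected count unit: raw counts of whole numbers for 2980 locus tags, with replicates in separate columns, so that rounding changed nothing. Its last 3 lines carry no locus tag. They hold the column sum, a larger total of unstated meaning and the ratio of both, and were left out of every test. Totals ran from 380360 to 4215572 counts per library, and 94.69 to 98.06% of each larger total lay in the table. A count of 0 allows up to 3 counts, and counting error is the only error this covers. The terms set for structural RNA matched 1 locus tag, which was not treated as an rRNA or tRNA gene, so none was removed.

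Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 9 groups, which left 2936 tested and 44 not tested. Libraries were scaled by TMM, and a single quasi-likelihood model with 1 mean per group was fitted to all 27 libraries (18 residual degrees of freedom, biological coefficient of variation 19.6%). The 10 comparisons of groups, 2 donor-by-stage interactions and 2 comparisons between times after FeCl2 were tested with glmQLFTest, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 14 tests answer separate questions and were not adjusted across each other. Standard errors came from the fold change and its F statistic.

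Gene lists for iron oxidation, sulfur oxidation, respiration, carbon fixation, translation, motility, stress defence and mobile elements were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Of 34 lists, 31 had at least 3 tested members. A further 14 lists, of neighbouring locus tags or of narrower product words, were added after product names had been seen and before any test. Lists were tested against other genes with camera (limma 3.58.1), with a preset correlation of 0.01 and again with the correlation estimated, and adjusted over the fixed and the added lists of each comparison separately. Each list was also adjusted over the list alone. Some fixed word searches took in other genes and are named here by what they held, such as metal-related genes with hydrogenases, and translation and Gre factors with no RNA polymerase gene. The phosphate, oxidative stress and DNA repair searches held 45, 54 and 17 genes, and whole words left 10, 25 and 10.

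Genes named per comparison were chosen by the following rule. Every measured member of cyc2, mto and the porin-cytochrome cluster PCC3 was named. So were the 5 largest rises and 5 largest falls among called genes with a product name, a mean of at least 20 CPM in the higher group and every replicate of the one group beyond every replicate of the other, and the 2 largest of each kind among all products. For each list described, up to 2 rises and 2 falls could be added as examples. For an interaction, the 5 largest called terms of each sign with a mean of 20 CPM in at least 1 group were named.

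Pairing by replicate number was checked. In 1 of 36 group pairs, late-log and mid-log Fe(II)-citrate, all 3 correlations of replicate deviations passed 0.1 (0.14, 0.12 and 0.28). The model had no pairing term, so its 23 genes there ignore pairing. A replicate block gave 15 over all groups and 244 over that pair. Tests on simulated data had the same depths and spread, with 200 of 2936 genes changed. Of 100 changed 2-fold, 66 to 87% were called between groups and 41 and 49% in interactions, and of those changed 4-fold 89 to 99%. False calls were 1.2 to 8.6% of calls, and broader change was not simulated.

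Alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, no low-count filter, a model of only the groups compared (own-group model), the replicate block, thinning of each library to 380360 counts, and each replicate left out in turn. Added after the data had been seen were the block with 2 groups, both shallow thiosulfate libraries left out, 4 libraries standing apart left out (stationary Fe(II)-citrate replicate 3, late-log thiosulfate replicate 3, 35 min replicate 1 and 90 min replicate 3), and 20 abundant genes removed. Reads outside the table were not analysed by gene. Agreement and sharing between responses were compared with counts for independent lists and with 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.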

Results

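RNA was sequenced from 27 samples of Sideroxydans lithotrophicus ES-1, a bacterium that grows with oxygen at the expense of Fe(II) or thiosulfate and fixes CO2. The libraries fell into 9 groups of 3 replicates. For 6 groups, cells were grown on Fe(II)-citrate or on thiosulfate and taken at mid-log, late-log or stationary phase. For the other 3 groups, FeCl2 was added to stationary thiosulfate cultures and cells were taken after 15, 35 or 90 min; the stationary thiosulfate libraries served as the state before the addition. No culture received a mock addition.

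Of the locus tags with counts, 2936 were tested and 44 were too low. Total counts per library ran from 380360 (stationary thiosulfate replicate 1) to 4215572 (mid-log thiosulfate replicate 1). Next shallowest were late-log thiosulfate replicate 1 (401993) and 35 min replicate 2 (761981). Totals lay between 1014376 and 1881952 in the Fe(II)-citrate libraries. Within groups, the correlation of log CPM between replicates across genes ran from 0.944 to 0.983, with genes not being independent replicates. Values for single genes are log2 fold changes ± standard error from all 27 libraries, 3 per group, and each p for a gene is edgeR's quasi-likelihood p with Benjamini-Hochberg adjustment. An own-group model holds only the groups compared.

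**Figure D1:**
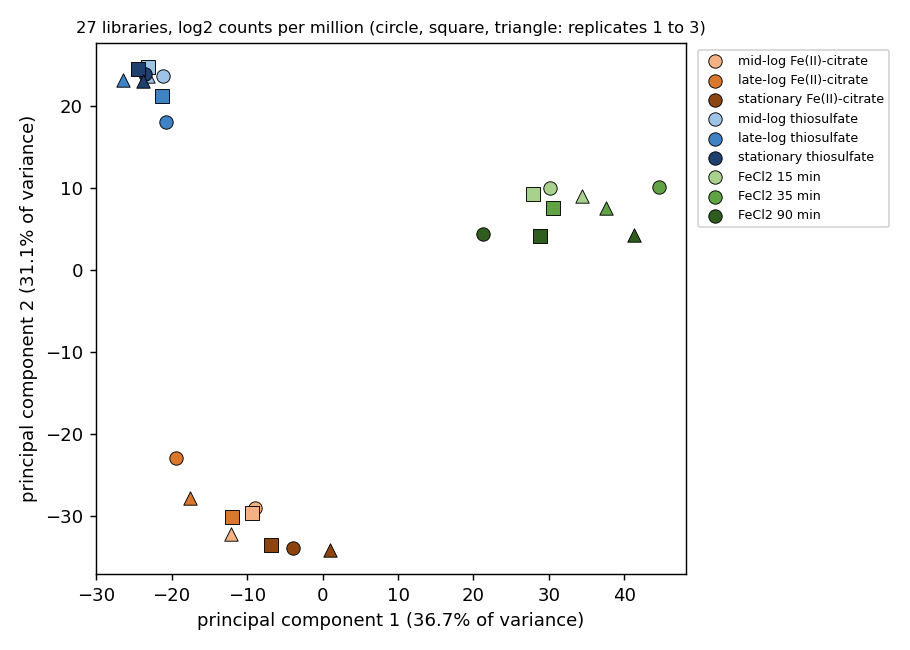
Each of the 27 libraries (points) on the first 2 principal components of log2 CPM (axes in component units), with colours for groups and shapes for replicates. They held 36.7% and 31.1% of the variance.

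The first question was which transcripts differed between the electron donors at each growth stage. At mid-log on Fe(II)-citrate, the sulfate adenylyltransferase subunit genes Slit_1034 (7.00 ± 0.34, adjusted p = 3.1e-14) and Slit_1035 (5.87 ± 0.30, adjusted p = 4.2e-14), the reductase gene Slit_1033 (6.96 ± 0.38) and the ferredoxin-type sulfite reductase gene Slit_1032 (6.81 ± 0.39) rose. Of the cyc2 genes, whose outer membrane cytochromes are known from Fe(II) oxidisers, Slit_0264 (4.34 ± 0.22) and Slit_0265 (4.59 ± 0.39) rose and Slit_0263 (-1.24 ± 0.38) fell. How reads shared by the cyc2 copies were assigned is not stated in the sources used here, so their separate values are uncertain. The conserved hypothetical Slit_2184 (7.99 ± 0.42) rose too, and the phage transposition gene Slit_0192 (5.28 ± 0.66) from a mean of 0.579 CPM.

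Iron permease FTR1 Slit_2529 (-4.44 ± 0.42) and a gene of the Fur family of metal-responsive repressors Slit_2531 (-4.13 ± 0.33) fell on Fe(II)-citrate. Lower were the sigma-24 factor gene Slit_1702 (-3.68 ± 0.28), the chemoreceptor gene Slit_1591 (-3.89 ± 0.41), and the neighbours Slit_2762 (-3.72 ± 0.27) of the DoxX family, Slit_2763 (-5.34 ± 0.38) and Slit_2765 (-5.95 ± 0.38), the last 2 uncharacterised. The 4 genes of PCC3, a porin-cytochrome cluster with multiheme cytochromes, fell: Slit_0867 (-2.81 ± 0.32), Slit_0868 (-1.40 ± 0.41), Slit_0869 (-1.26 ± 0.24) and Slit_0870 (-1.73 ± 0.46). For the list, camera adjusted p = 0.033, or 0.27 with estimated correlation, and 0.0537 without mid-log Fe(II)-citrate replicate 1. The call of Slit_0868 ended without mid-log Fe(II)-citrate replicate 1 (-1.14). It also ended after thinning (-0.996). None of the mto genes, which encode the decaheme cytochrome and porin of another outer membrane conduit with a periplasmic cytochrome and a CymA-like protein, passed the edgeR test. Their values were Slit_2495 (-0.06 ± 0.80, adjusted p = 0.956), Slit_2496 (0.22 ± 0.73, adjusted p = 0.823), Slit_2497 (2.94 ± 1.38) and Slit_2498 (1.197 ± 1.80). Calls were gained with DESeq2 by Slit_2497 (3.01), and in the own-group model by Slit_2497 (2.97).

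Genes of translation and energy conversion were higher on Fe(II)-citrate. Among the lists, 46 of 55 ribosomal protein, 11 of 16 translation and Gre factor and 8 of 11 ATP synthase (2 fell) genes rose (48, 11 and 8 adjusted over the list alone), camera adjusted p = 5.9e-13, 0.0014 and 0.0014, or 0.242 to 0.28 with estimated correlation. In the lists, 7 of 14 RuBisCO and Calvin cycle, 10 of 12 NADH-quinone oxidoreductase (1 fell), 9 of 16 chaperone (2 fell) and 16 of 36 flagella (1 fell) genes rose (7, 10, 9 and 16 adjusted over the list alone), camera adjusted p = 0.0014, 0.00714, 0.0014 and 0.00171, or 0.165 to 0.28 with estimated correlation. All 7 genes of the alternative complex III locus, for a complex that passes electrons between quinones and cytochromes, had a median of 1.80, and a Mu-like prophage region one of 3.36. List by list, 7 of 7 alternative complex III locus, 4 of 4 b561 locus, 53 of 59 Mu-like prophage (1 fell) and 2 of 3 cyc2 (1 fell) genes rose (fixed list 2 adjusted over the list alone), camera adjusted p = 6.1e-04, 1.5e-07, 6.6e-19 and 0.0014, or 0.29, 0.00559, 8.0e-06 and 0.0467 with estimated correlation. The sox locus, which serves thiosulfate oxidation, had a median of -2.21. By list, 5 of 5 sox locus, 6 of 13 dsr locus, 12 of 16 hydrogenase and transhydrogenase and 12 of 19 metal-related (3 rose) genes fell (fixed lists 12 and 12 adjusted over the list alone), camera adjusted p = 3.8e-04, 0.0203, 0.00146 and 0.013, or 0.106 to 0.513 with estimated correlation. The dsr call ended without mid-log Fe(II)-citrate replicate 1 (adjusted p = 0.0593) or 3 (0.105). Not called were the apr and sat locus, with 2 of 8 genes lower (camera adjusted p = 0.0965), the sulfur relay list, with 2 of 9 lower and 1 higher (0.543), and the sulfite and persulfide search, with 4 of 19 lower and 7 higher (0.146), the same counts as adjusted over the list alone.

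In all, 1502 of 2936 genes passed the edgeR test between donors at mid-log, 712 higher and 790 lower on Fe(II)-citrate, and 700 of them differed at least 2-fold. DESeq2 gave 1433 genes, 823 higher and 610 lower. With its scaling the median of all genes moved by 0.11 from -0.09.

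At late-log, Slit_1032 (6.40 ± 0.40, adjusted p = 3.4e-12), Slit_1033 (6.08 ± 0.39, adjusted p = 3.4e-12), Slit_1034 (5.96 ± 0.34) and Slit_1035 (5.68 ± 0.32) were again higher on Fe(II)-citrate, with the neighbouring membrane protein gene Slit_1031 (6.29 ± 0.38). The cyc2 genes Slit_0264 (2.70 ± 0.20) and Slit_0265 (2.68 ± 0.37) rose, while Slit_0263 (-0.08 ± 0.37) did not pass the test. For the list, camera adjusted p = 0.0067, or 0.0718 with estimated correlation. The phage transposition gene Slit_0192 (4.14 ± 0.57) rose. Falls on Fe(II)-citrate were in the sulfate adenylyltransferase gene Slit_1712 (-4.03 ± 0.70), which serves sulfite oxidation, the multicopper oxidase gene Slit_1817 (-3.59 ± 0.59), the sigma-24 factor gene Slit_1702 (-3.53 ± 0.27) and the histone-like gene Slit_1158 (-3.48 ± 0.29). The baseplate gene Slit_1898 (-3.50 ± 0.36) and the uncharacterised Slit_2765 (-5.34 ± 0.37) and Slit_1890 (-4.51 ± 0.66) fell as well, Slit_1890 with a mean of 1.25 CPM on Fe(II)-citrate. Late-log thiosulfate replicate 3 stood apart, and without it Slit_1712 was -2.77 and Slit_1817 -2.59, both still called.

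All PCC3 genes fell, namely Slit_0867 (-1.88 ± 0.29), Slit_0868 (-1.90 ± 0.39), Slit_0869 (-1.17 ± 0.24) and Slit_0870 (-1.52 ± 0.43), camera adjusted p = 0.0325, or 0.337 with estimated correlation. The list call ended without late-log Fe(II)-citrate replicate 2 (adjusted p = 0.067) or late-log thiosulfate replicate 1 (0.0619) or 3 (0.0613). The mto genes Slit_2495 (-2.56 ± 0.64, adjusted p = 0.0023), Slit_2496 (-3.01 ± 0.69, adjusted p = 0.00108), Slit_2497 (-3.90 ± 0.99) and Slit_2498 (-3.77 ± 1.21) passed the test as lower on Fe(II)-citrate, while for the list camera adjusted p = 0.326, or 0.702 with estimated correlation. Without late-log thiosulfate replicate 3, the calls of Slit_0870 (-0.96), Slit_2495 (-0.53), Slit_2496 (-0.37) and Slit_2497 (0.59) ended. The call of Slit_2498 ended without late-log Fe(II)-citrate replicate 1 (-3.47) or late-log thiosulfate replicate 3 (2.59). It also ended with DESeq2 (-3.39).

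Sulfur oxidation genes were lower on Fe(II)-citrate as whole loci, with medians of -2.51 for the dsr locus, -2.94 for sox and -3.21 for apr and sat, which serves sulfite oxidation. Without late-log thiosulfate replicate 3 they were -1.86, -2.68 and -2.43. Among the lists, 13 of 13 dsr locus, 5 of 5 sox locus, 8 of 8 apr and sat locus, 7 of 9 sulfur relay (1 rose), 10 of 19 metal-related (1 rose) and 7 of 13 hydrogenase genes fell (fixed lists 7 and 10 adjusted over the list alone), camera adjusted p = 6.1e-07, 3.0e-07, 2.1e-04, 0.0138, 0.0138 and 0.0114, or 0.109 to 0.535 with estimated correlation. The subunit genes Slit_1686 (-3.33) and Slit_1685 (-2.88) of the dissimilatory-type sulfite reductase were among them, at -1.94 and -1.86 without that replicate. In the lists, 7 of 7 alternative complex III locus, 3 of 4 b561 locus, 49 of 59 Mu-like prophage and 3 of 10 DNA repair genes rose, camera adjusted p = 4.4e-04, 0.00551, 2.5e-14 and 0.0247, or 0.214, 0.157, 5.8e-04 and 0.157 with estimated correlation. List by list, 17 of 36 flagella genes rose (19 adjusted over the list alone), camera adjusted p = 3.8e-05, or 0.0922 with estimated correlation. Of the ribosomal protein genes, 5 of 55 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.295, or 0.894 with estimated correlation. Between donors at late-log, 1118 genes passed the edgeR test, 528 higher and 590 lower on Fe(II)-citrate, 497 of them at least 2-fold. With RLE scaling 608 were higher and 547 lower.

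In stationary phase, Slit_1031 (7.10 ± 0.38, adjusted p = 2.0e-13), Slit_1032 (6.61 ± 0.41, adjusted p = 2.0e-12), Slit_1033 (7.08 ± 0.41), Slit_1034 (5.72 ± 0.33) and Slit_1035 (6.16 ± 0.33) rose on Fe(II)-citrate, beside the hypothetical Slit_2184 (7.38 ± 0.41). The sox genes Slit_1700 (-5.42 ± 0.36), a cytochrome, Slit_1699 (-5.21 ± 0.37), a twin-arginine signal protein, and Slit_1698 (-5.03 ± 0.39), SoxZ, which carries sulfur intermediates, fell. The sigma-24 gene Slit_1702 (-4.75 ± 0.30) and the chemotaxis gene Slit_1587 (-4.69 ± 0.45), a CheW coupling protein, fell too, and the phage gene Slit_0192 (5.49 ± 0.73) rose. The cyc2 genes Slit_0264 (2.18 ± 0.20) and Slit_0265 (3.10 ± 0.38) rose and Slit_0263 (-1.16 ± 0.38) fell. For the list, camera adjusted p = 0.101, or 0.368 with estimated correlation. The call of Slit_0263 ended without stationary Fe(II)-citrate replicate 1 (-0.97) or 2 (-0.92). All PCC3 genes fell, with Slit_0867 (-2.30 ± 0.30), Slit_0868 (-1.88 ± 0.41), Slit_0869 (-1.99 ± 0.26) and Slit_0870 (-1.75 ± 0.46), but for the list camera adjusted p = 0.0546, or 0.368 with estimated correlation. The mto genes did not pass the test, with Slit_2495 (-0.28 ± 1.05), Slit_2496 (-0.97 ± 0.84), Slit_2497 (-0.50 ± 1.59) and Slit_2498 (0.64 ± 2.53); camera adjusted p = 0.943, or 0.967 with estimated correlation. Further calls came in the own-group model for Slit_2496 (-0.94).

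The sox locus had a median of -5.03. By list, 5 of 5 sox locus, 13 of 13 dsr locus and 8 of 8 apr and sat locus genes fell, camera adjusted p = 1.3e-09, 0.00322 and 0.0138, or 0.0482, 0.401 and 0.401 with estimated correlation. Among the lists, 11 of 16 hydrogenase and transhydrogenase (1 rose) and 5 of 10 hemerythrin-like genes fell (fixed list 11 adjusted over the list alone), camera adjusted p = 0.00573 and 0.0159, or 0.368 and 0.099 with estimated correlation. In the lists, 47 of 55 ribosomal protein, 10 of 16 translation and Gre factor (1 fell), 9 of 11 ATP synthase (2 fell) and 9 of 16 chaperone (3 fell) genes rose (48, 11, 9 and 9 adjusted over the list alone), camera adjusted p = 6.0e-10, 0.00232, 0.0255 and 0.0171, or 0.368 with estimated correlation. List by list, 7 of 7 alternative complex III locus, 4 of 4 b561 locus, 50 of 59 Mu-like prophage (1 fell) and 4 of 10 DNA repair (2 fell) genes rose, camera adjusted p = 4.4e-04, 0.00193, 1.2e-12 and 0.0159, or 0.224, 0.0824, 0.00126 and 0.0824 with estimated correlation. Between donors in stationary phase, 1635 genes passed the edgeR test, 781 higher and 854 lower on Fe(II)-citrate, 842 at least 2-fold. With RLE scaling 874 were higher and 748 lower.

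**Figure D2:**
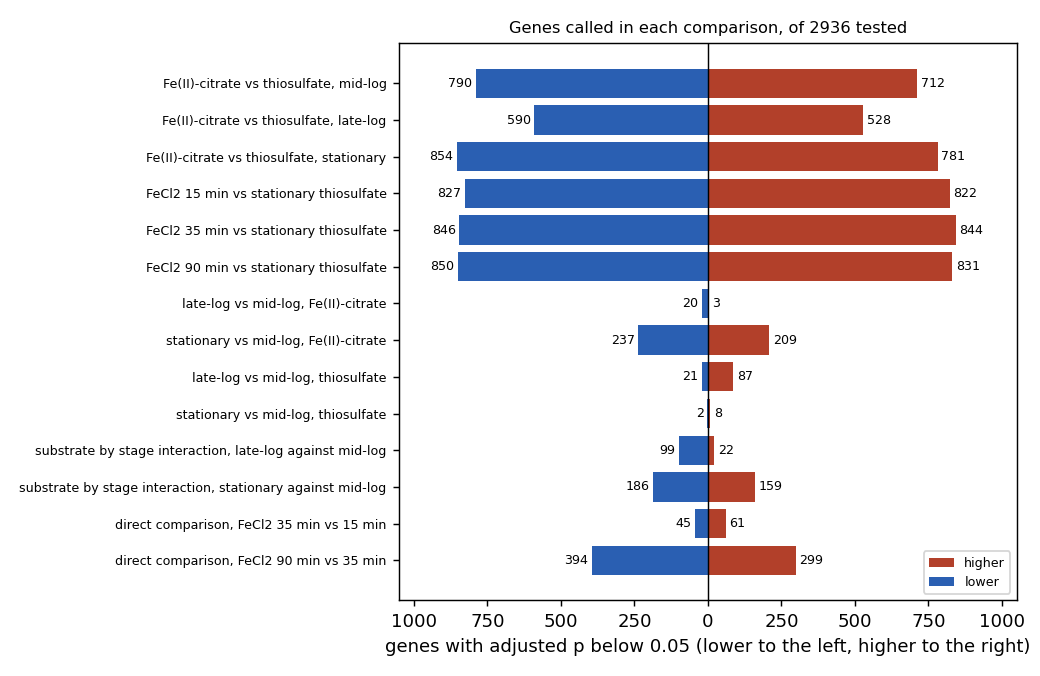
Number of genes past an adjusted p of 0.05 in edgeR (horizontal axis, genes) that were higher or lower, for each comparison. The largest count is 1690 genes at 35 min after FeCl2 and the smallest is 10 between stationary and mid-log thiosulfate cultures.

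The next question was which transcripts differed between growth stages on 1 donor. From mid-log to late-log on Fe(II)-citrate, the RuBisCO gene Slit_0022 (-1.57 ± 0.34, adjusted p = 0.0263), which fixes CO2, and its neighbours Slit_0023 (-1.58 ± 0.33, adjusted p = 0.0263), CbbQ-like, and Slit_0024 (-1.58 ± 0.27) fell. The outer membrane efflux gene Slit_1863 (-1.73 ± 0.34) and its membrane fusion partner Slit_1864 (-1.46 ± 0.32) fell as well. The cytochrome gene Slit_2042 (1.98 ± 0.43), the porin gene Slit_1664 (0.92 ± 0.17) and the SMC domain gene Slit_2189 (0.78 ± 0.18) rose. No cyc2, mto or PCC3 gene passed the edgeR test: the cyc2 values were Slit_0263 (1.08), Slit_0264 (-0.46) and Slit_0265 (-1.16), the mto values Slit_2495 (-0.10), Slit_2496 (-0.41), Slit_2497 (-1.18) and Slit_2498 (-0.70), and the PCC3 values Slit_0867 (0.62), Slit_0868 (-0.05), Slit_0869 (0.03) and Slit_0870 (0.32). Calls were gained with DESeq2 by Slit_0263 (1.07), and in the own-group model by Slit_0263 (1.10) and Slit_0265 (-1.15), and with the block in that model by Slit_0263 (1.064), Slit_0265 (-1.17) and Slit_2497 (-1.15). By list, 7 of 55 ribosomal protein, 2 of 4 b561 locus and 2 of 14 RuBisCO and Calvin cycle genes fell (fixed lists 36 and 2 adjusted over the list alone), camera adjusted p = 5.6e-39, 7.8e-07 and 0.00358, or 0.235, 0.0127 and 0.485 with estimated correlation. With no single member past the edgeR threshold, camera placed ATP synthase, translation and Gre factors and RNA polymerase core below other genes (camera adjusted p = 2.9e-05 to 0.00358, or 0.074 to 0.485 with estimated correlation) and hydrogenases above them (camera adjusted p = 2.9e-04, or 0.0922 with estimated correlation).

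Here 23 genes passed the edgeR test, 3 higher and 20 lower at late-log. The count was 0 without mid-log Fe(II)-citrate replicate 1 (unadjusted p under 0.05 for 289 genes) or late-log Fe(II)-citrate replicate 1 (210) or 3 (228), while DESeq2 with all libraries gave 65. It was 2 without mid-log replicate 2, 9 without mid-log replicate 3 and 71 without late-log replicate 2. The own-group model gave 57 genes. With the block it gave 244 (73 higher, 171 lower) and all groups 15, so the step's size stays open. The call of Slit_0022 ended without mid-log replicate 1 (-1.45) or 2 (-1.53) or late-log replicate 1 (-1.44) or 3 (-1.54). Slit_0023 lost its call without mid-log replicate 1 (-1.44) or 2 (-1.56) or late-log replicate 1 (-1.50) or 3 (-1.54). For Slit_0024, the call ended without mid-log replicate 1 (-1.48) or late-log replicate 1 (-1.49) or 3 (-1.51). That of Slit_1863 ended without mid-log replicate 1 (-1.60) or late-log replicate 1 (-1.39) or 3 (-1.75). The call of Slit_1864 ended without mid-log replicate 1 (-1.36), 2 (-1.57) or 3 (-1.44) or late-log replicate 1 (-1.16) or 3 (-1.46). Slit_2042 lost its call without mid-log replicate 1 (2.00), 2 (1.86) or 3 (2.08) or late-log replicate 1 (1.65) or 3 (1.84). For Slit_1664, the call ended without mid-log replicate 1 (0.93) or 2 (0.88) or late-log replicate 1 (0.74) or 3 (0.93). That of Slit_2189 ended without mid-log replicate 1 (0.90), 2 (0.77) or 3 (0.69) or late-log replicate 1 (0.60) or 3 (0.84).

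From mid-log to stationary phase on Fe(II)-citrate, the P-II regulatory protein gene Slit_0065 (3.01 ± 0.36, adjusted p = 4.7e-06), the ammonium transporter gene Slit_0066 (1.62 ± 0.20, adjusted p = 4.7e-06) and the hypothetical Slit_0064 (3.05 ± 0.26) beside them rose. The chemoreceptor gene Slit_0069 (1.76 ± 0.40) and the NmrA family gene Slit_2237 (1.75 ± 0.28) rose too. The sox genes Slit_1698 (-1.97 ± 0.39), Slit_1699 (-2.10 ± 0.37) and Slit_1700 (-2.27 ± 0.35) and the chemotaxis genes Slit_1585 (-1.91 ± 0.43) and Slit_1587 (-1.95 ± 0.56) fell, with the uncharacterised Slit_0485 (-2.20 ± 0.45). Without mid-log replicate 1, Slit_1698 was -1.20 and Slit_1699 -1.39. The NMT1/THI5 domain gene Slit_0090 (1.74 ± 0.56) rose. The call of Slit_0090 ended without mid-log replicate 1 (1.68), 2 (1.71) or 3 (1.81) or stationary replicate 2 (1.78) or 3 (1.62). Slit_1587 lost its call without stationary replicate 3 (-1.33). The call of Slit_1587 also ended in the own-group model (-1.95). Among the cyc2 genes, Slit_0264 (-1.17 ± 0.19) and Slit_0265 (-1.05 ± 0.34) fell and Slit_0263 (0.07 ± 0.37) did not pass the test. The call of Slit_0265 ended without mid-log replicate 1 (-1.0), 2 (-1.07) or 3 (-1.07) or stationary replicate 2 (-1.03) or 3 (-0.64). It also ended in the own-group model (-1.06). Without stationary replicate 1, Slit_0265 was -1.63. The mto values were Slit_2495 (-0.997), Slit_2496 (-1.20), Slit_2497 (-1.94) and Slit_2498 (-1.27) and the PCC3 values Slit_0867 (0.48), Slit_0868 (-0.25), Slit_0869 (-0.62) and Slit_0870 (-0.06), none past the threshold. Gained calls came in the own-group model for Slit_2496 (-1.20) and Slit_2497 (-1.93).

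Among the lists, 5 of 5 sox locus, 9 of 22 type IV pili, 9 of 36 flagella and 2 of 3 cyc2 genes fell (fixed lists 9, 13 and 2 adjusted over the list alone), camera adjusted p = 9.8e-07, 6.7e-04, 6.7e-04 and 0.0436, or 0.182, 0.00853, 0.242 and 0.242 with estimated correlation. The cyc2 call ended without mid-log replicate 3 (adjusted p = 0.0672) or stationary replicate 2 (0.104). In this comparison 446 genes passed the edgeR test, 209 higher and 237 lower in stationary phase, 102 at least 2-fold. The count was 199 without stationary replicate 3, and 263 and 228 without mid-log replicates 1 and 2.

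On thiosulfate, from mid-log to late-log, the rubrerythrin gene Slit_0302 (5.35 ± 0.83, adjusted p = 2.9e-04), for a diiron protein linked to peroxide removal, and the chaperone gene Slit_2129 (2.03 ± 0.37, adjusted p = 0.001), for the DnaK partner GrpE, rose. Of the cyc2 genes Slit_0264 (1.18 ± 0.20) rose, and Slit_0263 (-0.08) and Slit_0265 (0.75) did not pass the test. The Crp/Fnr family regulator gene Slit_2566 (-1.24 ± 0.17), Slit_2762 (-1.26 ± 0.20) of the DoxX family, Slit_2763 (-1.42 ± 0.26), the PAS sensor gene Slit_2016 (-1.12 ± 0.23) and the diguanylate cyclase gene Slit_2565 (-0.88 ± 0.18) fell. The NnrS family gene Slit_1132 (-1.10 ± 0.27) fell. The call of Slit_1132 ended without mid-log replicate 1 (-1.02) or 3 (-1.05) or late-log replicate 2 (-0.98) or 3 (-1.21). Calls also ended in the own-group model for Slit_2565 (-0.83) and Slit_1132 (-1.10) and after thinning for Slit_1132 (-0.91). The PCC3 values Slit_0867 (-0.31), Slit_0868 (0.45), Slit_0869 (-0.06) and Slit_0870 (0.11) did not pass the test.

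All 4 mto genes passed the test as higher, with Slit_2495 (2.40 ± 0.56, adjusted p = 0.01), Slit_2496 (2.82 ± 0.65, adjusted p = 0.00988), Slit_2497 (5.67 ± 1.064) and Slit_2498 (4.27 ± 1.09), camera adjusted p = 0.00288, or 0.301 with estimated correlation. The sulfite reductase gene Slit_1686 (2.01 ± 0.56), the cytochrome gene Slit_1877 (2.51 ± 0.71) and the C_GCAxxG_C_C family gene Slit_2273 (2.83 ± 0.81) rose. The call of Slit_2495 ended without mid-log replicate 1 (2.19) or late-log replicate 3 (0.39). Slit_2496 lost its call without mid-log replicate 3 (2.62) or late-log replicate 3 (0.20). For Slit_2497, the call ended without late-log replicate 3 (1.21). That of Slit_2498 ended without mid-log replicate 1 (4.04), 2 (4.13) or 3 (4.61) or late-log replicate 3 (-2.06). The call of Slit_1686 ended without mid-log replicate 1 (2.02), 2 (2.03) or 3 (1.98) or late-log replicate 3 (0.64). Slit_1877 lost its call without mid-log replicate 1 (2.77), 2 (2.27) or 3 (2.55) or late-log replicate 1 (2.55) or 3 (1.86). For Slit_2273, the call ended without mid-log replicate 1 (2.34), 2 (3.32) or 3 (2.92) or late-log replicate 1 (2.90) or 3 (1.51). Alternatives also ended calls after thinning for Slit_2495 (2.06), Slit_2498 (4.15) and Slit_1877 (2.42), in the own-group model for Slit_2495 (2.34), Slit_2496 (2.77), Slit_2497 (5.56), Slit_2498 (4.13), Slit_1686 (2.01) and Slit_2273 (2.76), with DESeq2 for Slit_2498 (3.93) and Slit_2273 (2.69) and with the block for Slit_1686 (2.07) and Slit_2273 (2.88). In that library 14 genes stood over 4-fold above both other replicates, among them Slit_0302 at 8570 CPM against 752 and 129, and Slit_1686 at 20100 CPM against 4288 and 2623. Without it, Slit_0302 stayed past the threshold at 2.33.

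In the lists, 6 of 16 chaperone, 6 of 27 mobile element, 6 of 59 Mu-like prophage (1 fell) and 7 of 24 c-type cytochrome genes rose (fixed lists 6, 8 and 10 adjusted over the list alone), camera adjusted p = 1.3e-07, 5.1e-07, 1.6e-09 and 5.6e-05, or 0.0127, 0.0122, 3.3e-04 and 0.0584 with estimated correlation. List by list, 1 of 13 dsr locus, 2 of 4 b561 locus, 1 of 11 ATP synthase, 1 of 9 cbb3 oxidase locus and 1 of 3 cyc2 genes rose (fixed lists 7 and 1 adjusted over the list alone), camera adjusted p = 2.2e-05, 6.1e-04, 2.1e-04, 0.00334 and 0.00769, or 0.0584 to 0.356 with estimated correlation. With no single member called, camera placed ribosomal proteins, the sox locus and the apr and sat locus above other genes (camera adjusted p = 3.5e-07 to 0.00334, or 0.356 to 0.481 with estimated correlation). Without late-log replicate 3, the list calls of mto (adjusted p = 0.474), dsr (0.132), sox (0.0557) and apr and sat (0.14) ended. In all, 108 genes passed the edgeR test, 87 higher and 21 lower at late-log, 75 at least 2-fold. The count was 57 without late-log replicate 3, 58 without mid-log replicate 1 and 64 without mid-log replicate 3.

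From mid-log to stationary phase on thiosulfate, few transcripts differed. The cyc2 gene Slit_0264 (0.99 ± 0.20, adjusted p = 0.0181), the c-type cytochrome gene Slit_1353 (1.09 ± 0.25, adjusted p = 0.0495), the cyclic di-GMP enzyme gene Slit_2271 (0.77 ± 0.16) and the hypothetical Slit_0152 (1.42 ± 0.20) and Slit_1947 (1.19 ± 0.25) rose, and Slit_1277 (-0.70 ± 0.14), for a RseC-type regulator of the envelope stress factor sigma E, fell. The values of Slit_0263 (-0.01) and Slit_0265 (0.45), of the mto genes Slit_2495 (-0.78), Slit_2496 (-0.01), Slit_2497 (1.504) and Slit_2498 (-0.72), and of the PCC3 genes Slit_0867 (-0.02), Slit_0868 (0.23), Slit_0869 (0.12) and Slit_0870 (-0.04) did not pass the test. For the cyc2 list, with 1 gene called, camera adjusted p = 0.0249, or 0.182 with estimated correlation, and the call ended without mid-log replicate 1 (adjusted p = 0.101) or stationary replicate 1 (0.0655) or 2 (0.0724). With no single member called, camera placed higher the sox, b561 and cbb3 loci and the Mu-like prophage (camera adjusted p = 8.5e-05 to 0.00246, or 0.12 to 0.165 with estimated correlation), and lower cytochrome c maturation (camera adjusted p = 2.1e-04, or 0.182 with estimated correlation).

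Here 10 genes passed the edgeR test, 8 higher and 2 lower in stationary phase. The count was 0 without stationary replicate 3 (unadjusted p under 0.05 for 257 genes), 6 and 2 without stationary replicates 1 and 2, and 1, 1 and 4 without mid-log replicates 1, 2 and 3. The call of Slit_0264 ended without mid-log replicate 1 (0.91) or 2 (0.99) or stationary replicate 1 (0.99), 2 (1.007) or 3 (0.99). Slit_1353 lost its call without mid-log replicate 1 (1.10), 2 (1.09) or 3 (1.07) or stationary replicate 1 (0.85), 2 (1.19) or 3 (1.21). For Slit_2271, the call ended without mid-log replicate 1 (0.69), 2 (0.78) or 3 (0.85) or stationary replicate 2 (0.73) or 3 (0.75). That of Slit_0152 ended without stationary replicate 3 (1.16). The call of Slit_1947 ended without mid-log replicate 1 (1.14), 2 (1.31) or 3 (1.11) or stationary replicate 2 (1.13) or 3 (1.13). Slit_1277 lost its call without mid-log replicate 1 (-0.75), 2 (-0.66) or 3 (-0.69) or stationary replicate 1 (-0.61), 2 (-0.77) or 3 (-0.75). Calls also ended with the block for Slit_1353 (1.09) and after thinning for Slit_1947 (1.14) and Slit_1277 (-0.60). DESeq2 gave 22 genes, 20 higher and 2 lower, thinning 6, and the own-group model 160, 105 higher and 55 lower.

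Whether the step between stages differed by donor was tested as an interaction, positive where the change on Fe(II)-citrate exceeded that on thiosulfate. For late-log against mid-log, the cyc2 genes Slit_0264 (-1.65 ± 0.28, adjusted p = 0.00161) and Slit_0265 (-1.91 ± 0.50, adjusted p = 0.0307) had negative terms that passed the test, and Slit_0263 (1.16) did not pass it. The rubrerythrin gene Slit_0302 (-4.97 ± 1.04) and its neighbours Slit_0303 (-4.73 ± 1.12) and Slit_0304 (-3.90 ± 1.09), the decaheme cytochrome gene Slit_2497 (-6.84 ± 1.72) and Slit_2273 (-4.06 ± 1.11) were also negative. The other mto terms were Slit_2495 (-2.50 ± 1.09), Slit_2496 (-3.23 ± 1.009) and Slit_2498 (-4.97 ± 2.38). Positive terms passed the test in Slit_2529 (1.86 ± 0.53) (iron permease FTR1), Slit_2762 (1.82 ± 0.41), Slit_2530 (1.65 ± 0.47), Slit_2566 (1.49 ± 0.24) and Slit_2016 (1.29 ± 0.33). The PCC3 terms Slit_0867 (0.93), Slit_0868 (-0.50), Slit_0869 (0.09) and Slit_0870 (0.21) did not pass the test. The call of Slit_0265 ended without mid-log Fe(II) replicate 1 (-1.86) or 2 (-1.94), late-log Fe(II) replicate 1 (-1.76) or 3 (-2.06), mid-log thiosulfate replicate 1 (-1.76) or 2 (-1.86) or late-log thiosulfate replicate 1 (-1.85). Slit_0302 lost its call without late-log thiosulfate replicate 3 (-1.95). For Slit_0303, the call ended without mid-log Fe(II) replicate 2 (-4.37), late-log Fe(II) replicate 3 (-4.47), mid-log thiosulfate replicate 1 (-4.63), 2 (-4.76) or 3 (-4.78) or late-log thiosulfate replicate 3 (-1.39). That of Slit_0304 ended without mid-log Fe(II) replicate 1 (-4.07), 2 (-3.59) or 3 (-4.00), late-log Fe(II) replicate 1 (-4.37), 2 (-3.79) or 3 (-3.64), mid-log thiosulfate replicate 1 (-3.81), 2 (-3.96) or 3 (-3.90) or late-log thiosulfate replicate 3 (-0.24). The call of Slit_2497 ended without mid-log Fe(II) replicate 1 (-6.74) or 2 (-6.83), late-log Fe(II) replicate 1 (-6.78) or 3 (-6.68), mid-log thiosulfate replicate 1 (-6.75), 2 (-6.70) or 3 (-7.06) or late-log thiosulfate replicate 3 (-2.39). Slit_2273 lost its call without mid-log Fe(II) replicate 2 (-2.84), late-log Fe(II) replicate 1 (-3.73) or 3 (-4.31), mid-log thiosulfate replicate 1 (-3.57), 2 (-4.54) or 3 (-4.15) or late-log thiosulfate replicate 1 (-4.12) or 3 (-2.73). For Slit_2529, the call ended without mid-log Fe(II) replicate 2 (1.69) or 3 (1.77), late-log Fe(II) replicate 1 (1.97) or 3 (1.07), mid-log thiosulfate replicate 1 (2.00), 2 (1.86) or 3 (1.72) or late-log thiosulfate replicate 1 (1.68) or 3 (1.75). That of Slit_2762 ended without mid-log Fe(II) replicate 2 (1.70) or late-log Fe(II) replicate 1 (1.59). The call of Slit_2530 ended without mid-log Fe(II) replicate 2 (1.39) or 3 (1.59), late-log Fe(II) replicate 1 (1.496) or 3 (1.29), mid-log thiosulfate replicate 1 (1.77), 2 (1.59) or 3 (1.57) or late-log thiosulfate replicate 1 (1.58) or 3 (1.43). Slit_2016 lost its call without mid-log Fe(II) replicate 2 (1.25), late-log Fe(II) replicate 1 (1.17), mid-log thiosulfate replicate 1 (1.27), 2 (1.31) or 3 (1.30) or late-log thiosulfate replicate 2 (0.95). Alternatives also ended calls in the own-group model for Slit_0303 (-4.73), Slit_0304 (-3.86), Slit_2529 (1.87) and Slit_2530 (1.66), with the block for Slit_0304 (-3.47), Slit_2529 (1.70) and Slit_2530 (1.58), after thinning for Slit_0304 (-3.95), Slit_2762 (1.34) and Slit_2016 (0.93), with DESeq2 for Slit_2273 (-3.92) and with RLE scaling for Slit_2530 (1.58). Gained calls came without late-log thiosulfate replicate 2 for Slit_2495 (-3.14) and Slit_2496 (-3.79), and with DESeq2 for Slit_2496 (-3.20).

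By list, 18 of 55 ribosomal protein, 6 of 16 chaperone, 6 of 11 ATP synthase, 2 of 16 translation and Gre factor and 5 of 24 c-type cytochrome terms were negative (45, 6, 8, 5 and 8 adjusted over the list alone), camera adjusted p = 3.9e-30, 1.2e-05, 1.3e-05, 2.8e-04 and 0.00139, or 0.108 to 0.255 with estimated correlation. Among the lists, 2 of 3 cyc2, 1 of 4 mto and 3 of 27 mobile element terms were negative (2, 4 and 5 adjusted over the list alone), camera adjusted p = 0.0279, 0.00726 and 0.00139, or 0.118 to 0.255 with estimated correlation. The cyc2 list call ended without late-log Fe(II)-citrate replicate 2 (adjusted p = 0.0638), mid-log thiosulfate replicate 1 (0.0586) or late-log thiosulfate replicate 3 (0.0516), and the mto list call without the last (0.261). In all, 121 terms passed the edgeR test, 22 positive and 99 negative. The count was 76 and 40 without mid-log Fe(II)-citrate replicates 1 and 2, 35 and 36 without late-log Fe(II)-citrate replicates 1 and 3, and 43, 42 and 43 without mid-log thiosulfate replicates 1, 2 and 3. It was 67 without late-log thiosulfate replicate 1, 57 without both shallow libraries, 190 without 4 libraries standing apart and 234 in the own-group model.

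For stationary against mid-log, the P-II gene Slit_0065 (3.54 ± 0.50, adjusted p = 4.6e-05) and the hypothetical Slit_0064 (2.93 ± 0.37, adjusted p = 1.4e-05) beside it, Slit_2237 (2.42 ± 0.44), Slit_1169 (2.64 ± 0.49) of the DUF6 transporters and Slit_2765 (2.67 ± 0.49) had positive terms. The sox genes Slit_1698 (-2.93 ± 0.50), Slit_1699 (-2.87 ± 0.47) and Slit_1700 (-3.21 ± 0.45), with Slit_0152 (-2.80 ± 0.32) and Slit_0485 (-3.58 ± 0.59), had negative ones. The cyc2 genes Slit_0264 (-2.16 ± 0.28) and Slit_0265 (-1.50 ± 0.50) were negative past the threshold and Slit_0263 (0.08) was not past it. The call of Slit_0265 ended without mid-log Fe(II) replicate 1 (-1.45), 2 (-1.52) or 3 (-1.52), stationary Fe(II) replicate 2 (-1.48) or 3 (-1.09), mid-log thiosulfate replicate 1 (-1.35) or 2 (-1.45) or stationary thiosulfate replicate 1 (-1.56), 2 (-1.34) or 3 (-1.56). It also ended after thinning (-1.60), with DESeq2 (-1.50) and in the own-group model (-1.48). The mto terms Slit_2495 (-0.22), Slit_2496 (-1.18), Slit_2497 (-3.44) and Slit_2498 (-0.56) and the PCC3 terms Slit_0867 (0.50), Slit_0868 (-0.48), Slit_0869 (-0.73) and Slit_0870 (-0.03) did not pass the test. Further calls came in the own-group model for Slit_2497 (-3.43). In the lists, 5 of 5 sox locus, 5 of 22 type IV pili, 4 of 36 flagella and 2 of 3 cyc2 terms were negative (fixed lists 8, 5 and 2 adjusted over the list alone), camera adjusted p = 7.1e-09, 0.00143, 0.0049 and 0.00672, or 0.112, 0.0132, 0.337 and 0.0684 with estimated correlation. In all, 345 terms passed the edgeR test, 159 positive and 186 negative. The count was 215 without stationary Fe(II)-citrate replicate 3, 221 without mid-log Fe(II)-citrate replicate 2 and 223 after thinning.

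The last set of comparisons asked which transcripts changed after FeCl2 reached stationary thiosulfate cultures. Within 15 min, the alternative complex III genes Slit_0640 (6.40 ± 0.41, adjusted p = 3.8e-12), Slit_0641 (5.54 ± 0.38, adjusted p = 1.1e-11), Slit_0642 (6.09 ± 0.40) and Slit_0643 (5.61 ± 0.32) rose, with all 7 genes of the locus past the threshold. The RuBisCO gene Slit_0022 (5.45 ± 0.41) and the activase-like Slit_0023 (5.53 ± 0.39) rose, Slit_0022 from a mean of 851 to 36970 CPM scaled by TMM. Iron permease FTR1 Slit_2529 (-4.40 ± 0.42) and the Fur family gene Slit_2531 (-4.60 ± 0.33) fell with the hypothetical Slit_2528 (-4.92 ± 0.47) and Slit_2530 (-4.97 ± 0.36) between and beside them. The peroxiredoxin-type gene Slit_1569 (-3.35 ± 0.21), the cyclase gene Slit_2198 (-3.42 ± 0.25) and the adenylylsulfate reductase subunit gene Slit_1714 (-3.17 ± 0.61), which serves sulfite oxidation, fell as well. Of the cyc2 genes, Slit_0265 (1.29 ± 0.36) rose and Slit_0263 (0.65) and Slit_0264 (-0.18) did not pass the test. Of the mto genes, Slit_2497 (3.08 ± 1.04) rose, and Slit_2495 (-0.09), Slit_2496 (1.58) and Slit_2498 (2.98) did not pass. The call of Slit_2497 ended without stationary thiosulfate replicate 3 (2.54). Calls were gained in the own-group model by Slit_0263 (0.65), Slit_2496 (1.62), Slit_2498 (3.00) and Slit_0870 (-0.84), and without 15 min replicate 3 by Slit_2496 (1.82). Of PCC3, Slit_0867 (-1.45 ± 0.26), Slit_0868 (-1.76 ± 0.39) and Slit_0869 (-1.25 ± 0.23) fell and Slit_0870 (-0.81) did not pass; without 15 min replicate 1, Slit_0868 was -2.69.

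List by list, 53 of 55 ribosomal protein (2 fell), 14 of 16 translation and Gre factor (1 fell), 9 of 11 ATP synthase (1 fell), 10 of 12 cytochrome c maturation and 11 of 14 RuBisCO and Calvin cycle (1 fell) genes rose (53, 14, 9, 10 and 11 adjusted over the list alone), camera adjusted p = 3.6e-34, 1.8e-10, 3.1e-06, 1.9e-04 and 0.00815, or 0.15 to 0.344 with estimated correlation. By list, 7 of 7 alternative complex III locus and 4 of 4 b561 locus genes rose, camera adjusted p = 2.4e-11 and 0.00852, or 0.0903 and 0.195 with estimated correlation. Among the lists, 5 of 5 sox locus and 9 of 13 hydrogenase genes fell, camera adjusted p = 0.0231 and 0.0102, or 0.318 and 0.195 with estimated correlation. At 15 min 1649 genes passed the edgeR test, 822 higher and 827 lower than before the addition, 823 at least 2-fold. Without a mock addition, what the handling itself changed is not separated here.

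At 35 min, the complex III genes Slit_0640 (6.84 ± 0.41, adjusted p = 1.1e-12), Slit_0641 (6.04 ± 0.39, adjusted p = 3.1e-12), Slit_0642 (5.2 ± 0.38) and Slit_0643 (5.54 ± 0.32) stayed high, and Slit_0024 (5.78 ± 0.33), with a von Willebrand factor domain and next to the RuBisCO genes, and the RNA helicase gene Slit_1660 (5.34 ± 0.39) rose. The mto genes Slit_2495 (5.07 ± 0.64) and Slit_2496 (3.64 ± 0.72) rose, while Slit_2497 (1.03) did not pass the test, and Slit_2498 had a mean of 0.682 CPM at 35 min against 1.78 before. The cyc2 genes Slit_0264 (0.99 ± 0.20) and Slit_0265 (2.35 ± 0.37) rose and Slit_0263 (0.76) did not pass. Gained calls came with DESeq2 for Slit_0263 (0.74), and without 35 min replicate 2 for Slit_0263 (0.97). FTR1 Slit_2529 (-4.11 ± 0.42), the Fur family gene Slit_2531 (-3.91 ± 0.33) and the chemotaxis-cluster genes Slit_1590 (-4.65 ± 0.54), a response regulator, and Slit_1592 (-3.96 ± 0.52), a sensor kinase, fell. The transport gene Slit_1194 fell to 3 reads over the 3 libraries, a mean of 0.549 CPM against 24.

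All PCC3 genes fell, with Slit_0867 (-1.88 ± 0.32, adjusted p = 1.6e-05), Slit_0868 (-1.09 ± 0.42, adjusted p = 0.0299), Slit_0869 (-1.02 ± 0.26) and Slit_0870 (-1.24 ± 0.49), camera adjusted p = 0.261, or 0.535 with estimated correlation. The call of Slit_0868 ended without stationary thiosulfate replicate 2 (-1.13) or 3 (-0.94) or 35 min replicate 1 (-0.96) or 3 (-1.16). Slit_0870 lost its call without stationary thiosulfate replicate 2 (-1.12) or 3 (-1.20) or 35 min replicate 1 (-0.83). Calls also ended after thinning for Slit_0868 (-0.95), Slit_0869 (-0.65) and Slit_0870 (-0.97). In the lists, 53 of 55 ribosomal protein (2 fell), 14 of 16 translation and Gre factor (1 fell), 9 of 11 ATP synthase (2 fell), 9 of 12 cytochrome c maturation and 12 of 14 RuBisCO and Calvin cycle (1 fell) genes rose (53, 14, 9, 9 and 12 adjusted over the list alone), camera adjusted p = 3.3e-37, 2.2e-10, 1.7e-06, 2.8e-04 and 0.00406, or 0.136 to 0.365 with estimated correlation. List by list, 7 of 7 alternative complex III locus and 4 of 4 b561 locus genes rose, camera adjusted p = 8.1e-12 and 1.6e-04, or 0.0473 and 0.0473 with estimated correlation. By list, 5 of 5 sox locus, 8 of 13 hydrogenase and 6 of 10 hemerythrin-like genes fell, camera adjusted p = 0.0192, 0.0192 and 0.024, or 0.159 to 0.374 with estimated correlation. At 35 min 1690 genes passed the edgeR test, 844 higher and 846 lower, 955 at least 2-fold. Leaving out 4 libraries standing apart gave 758 higher and 944 lower, and leaving out only 35 min replicate 1 gave 785 and 733.

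At 90 min, all 4 mto genes had risen, with Slit_2495 (6.54 ± 0.61, adjusted p = 9.0e-10), Slit_2496 (4.16 ± 0.71, adjusted p = 1.7e-05), Slit_2497 (4.53 ± 1.00) and Slit_2498 (6.62 ± 1.22), and so had their neighbour Slit_2494 (6.22 ± 0.62); for the mto list, camera adjusted p = 0.0831, or 0.518 with estimated correlation. The complex III genes Slit_0641 (5.63 ± 0.38), Slit_0642 (5.63 ± 0.39) and Slit_0643 (5.13 ± 0.32) stayed high. The chemotaxis-cluster genes Slit_1589 (-6.12 ± 0.47), an anti-sigma factor antagonist, Slit_1590 (-5.35 ± 0.49) and Slit_1587 (-4.86 ± 0.44) fell with FTR1 Slit_2529 (-4.96 ± 0.43) and the Fur family gene Slit_2531 (-5.44 ± 0.35). No cyc2 gene passed the edgeR test, with Slit_0263 (0.74 ± 0.37), Slit_0264 (-0.21 ± 0.20) and Slit_0265 (0.44 ± 0.36). Further calls came with DESeq2 for Slit_0263 (0.72). Of PCC3, Slit_0867 (-1.95 ± 0.27), Slit_0868 (-1.86 ± 0.39) and Slit_0869 (-1.50 ± 0.24) fell and Slit_0870 (-0.25) did not pass, camera adjusted p = 0.151, or 0.518 with estimated correlation. The RuBisCO gene Slit_0022 was still 2.76 above the state before the addition, at a mean of 5720 CPM, although for the Calvin cycle list, in which 8 of 14 rose and 1 fell (9 and 1 adjusted over the list alone), camera adjusted p = 0.0858, or 0.518 with estimated correlation.

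Among the lists, 12 of 26 chemotaxis (1 rose), 21 of 36 flagella (1 rose) and 10 of 22 type IV pili (4 rose) genes fell (12, 21 and 10 adjusted over the list alone), camera adjusted p = 8.3e-04, 0.00648 and 0.0385, or 0.134 to 0.226 with estimated correlation. In the lists, 5 of 5 sox locus, 7 of 10 hemerythrin-like and 10 of 13 hydrogenase genes fell, camera adjusted p = 0.00264, 0.0122 and 0.00264, or 0.144 to 0.208 with estimated correlation. List by list, 53 of 55 ribosomal protein (2 fell), 14 of 16 translation and Gre factor, 9 of 11 ATP synthase (2 fell) and 10 of 12 cytochrome c maturation genes rose (53, 14, 9 and 10 adjusted over the list alone), camera adjusted p = 4.1e-32, 3.7e-10, 9.8e-05 and 0.00104, or 0.134 to 0.216 with estimated correlation. By list, 7 of 7 alternative complex III locus, 4 of 4 b561 locus and 3 of 4 RNA polymerase core genes rose, camera adjusted p = 3.7e-12, 0.00869 and 0.00637, or 0.0718 to 0.144 with estimated correlation. At 90 min 1681 genes passed the edgeR test, 831 higher and 850 lower, 901 at least 2-fold, and 741 higher and 933 lower without the 4 libraries.

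**Figure D3:**
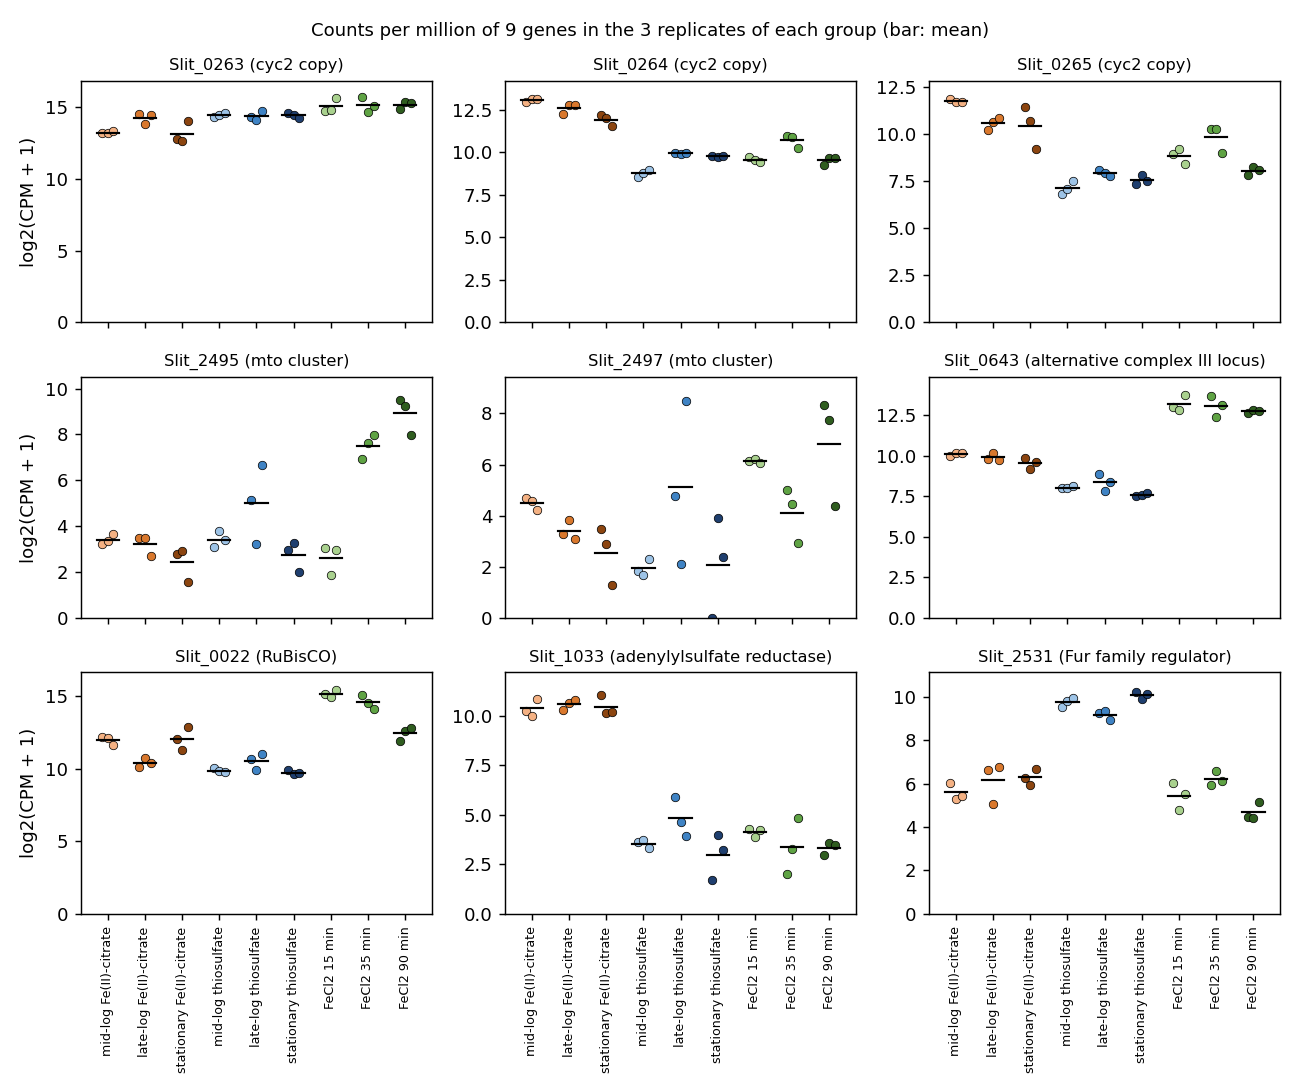
Expression of 9 genes in each library (vertical axis, log2 of CPM plus 1) by group, with points for the 3 replicates and bars for the mean of these log2 values. Slit_0022 rises from a mean of 851 CPM in stationary thiosulfate cultures to 36970 CPM at 15 min after FeCl2. CPM are scaled by TMM.

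**Figure D4:**
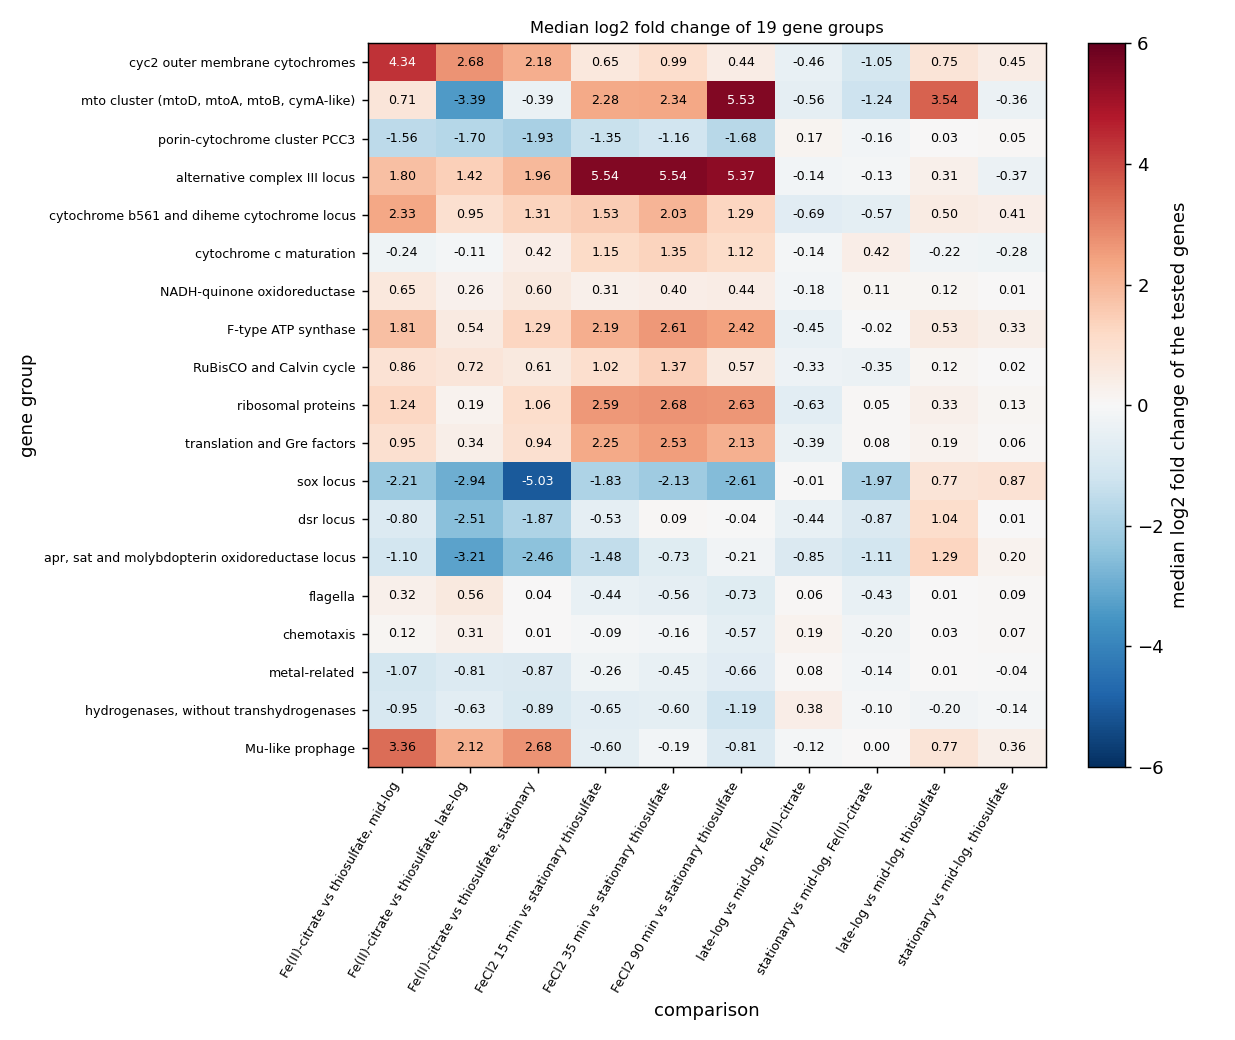
Median log2 fold change (colour and number) of 19 gene lists (vertical axis) in the 10 comparisons of groups (horizontal axis). The alternative complex III locus has medians of 5.54, 5.54 and 5.37 at 15, 35 and 90 min after FeCl2.

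Times after FeCl2 were also compared with each other. From 15 to 35 min, the CymA-like gene Slit_2495 (5.15 ± 0.63, adjusted p = 6.0e-06), the ferredoxin gene Slit_1710 (4.20 ± 0.59, adjusted p = 4.2e-05) of the apr and sat locus, and the sulfur relay genes Slit_1682 (3.65 ± 0.57), Slit_1683 (3.44 ± 0.53) and Slit_1684 (2.96 ± 0.56) of the dsr locus rose, as did cyc2 Slit_0264 (1.17 ± 0.20). The succinate dehydrogenase or fumarate reductase gene Slit_1839 (-1.45 ± 0.20), of the TCA cycle, fell. Falls in Slit_0567 (-1.97 ± 0.55), Slit_0496 (-1.32 ± 0.35), Slit_0393 (-1.15 ± 0.29), Slit_2151 (-1.30 ± 0.28) and Slit_1974 (-1.50 ± 0.36) passed the test. The call of Slit_0567 ended without 15 min replicate 3 (-1.51) or 35 min replicate 1 (-1.63), 2 (-2.13) or 3 (-2.31). Slit_0496 lost its call without 15 min replicate 1 (-1.26) or 2 (-1.36) or 35 min replicate 1 (-0.95) or 2 (-1.27). For Slit_0393, the call ended without 15 min replicate 2 (-1.09) or 35 min replicate 1 (-1.20) or 3 (-0.79). That of Slit_2151 ended without 15 min replicate 1 (-1.05) or 35 min replicate 3 (-1.11). The call of Slit_1974 ended without 35 min replicate 1 (-1.17) or 3 (-1.66). Alternatives also ended calls after thinning for Slit_0567 (-1.70), Slit_0496 (-1.25), Slit_0393 (-1.10) and Slit_2151 (-0.51) and in the own-group model for Slit_0567 (-1.96), Slit_0496 (-1.31), Slit_0393 (-1.17), Slit_2151 (-1.31) and Slit_1974 (-1.50). Without 35 min replicate 3, Slit_0496 was -2.19. The values of Slit_0263 (0.10), Slit_0265 (1.065), Slit_2496 (2.06), Slit_2497 (-2.04) and Slit_0867 (-0.43), Slit_0868 (0.67), Slit_0869 (0.23) and Slit_0870 (-0.43) did not pass it, nor did Slit_2498, with a mean of 12.3 CPM at 15 min. Calls were gained in the own-group model by Slit_0265 (1.05), Slit_2496 (2.04) and Slit_2497 (-2.07), and without 35 min replicate 3 by Slit_0265 (1.40) and Slit_2496 (2.41). Among the lists, 4 of 9 cbb3 oxidase locus, 2 of 4 b561 locus, 2 of 55 ribosomal protein and 2 of 4 RNA polymerase core genes rose (fixed list 3 adjusted over the list alone), camera adjusted p = 1.7e-06, 9.5e-04, 1.4e-04 and 0.00547, or 0.0524 to 0.942 with estimated correlation. In all 106 genes differed by edgeR, 61 higher and 45 lower at 35 min. The count was 52 without 35 min replicate 1, 66 without 15 min replicate 1 and 59 after thinning.

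From 35 to 90 min, genes of the mto region rose: Slit_2494 (4.62 ± 0.58, adjusted p = 6.5e-06), Slit_2495 (1.48 ± 0.42, adjusted p = 0.0126) and Slit_2497 (3.49 ± 1.03), with Slit_2498 going from a mean of 0.682 to 146 CPM, adjusted p = 0.00173; Slit_2496 (0.52) did not pass the test. The call of Slit_2495 ended without 35 min replicate 1 (1.23) or 90 min replicate 1 (1.17). Slit_2497 lost its call without 35 min replicate 3 (2.82) or 90 min replicate 1 (2.78). Calls also ended with DESeq2 for Slit_2495 (1.49) and in the own-group model for Slit_2497 (3.601). The sulfate adenylyltransferase gene Slit_1712 (2.96 ± 0.73) and the secretion and efflux genes Slit_0935 (2.56 ± 0.36) and Slit_1133 (3.05 ± 0.56) rose. The chemotaxis genes Slit_1583 (-2.78 ± 0.34), Slit_1584 (-3.29 ± 0.57), Slit_1585 (-3.61 ± 0.39) and Slit_1587 (-2.94 ± 0.52), the cbb3 oxidase gene Slit_0412 (-2.65 ± 0.36), and cyc2 Slit_0264 (-1.20 ± 0.20) and Slit_0265 (-1.91 ± 0.36) fell. The values of Slit_0263 (-0.02) and of PCC3, Slit_0867 (-0.06), Slit_0868 (-0.77), Slit_0869 (-0.48) and Slit_0870 (0.99), did not pass. Gained calls came after thinning for Slit_0869 (-1.03). In the lists, 13 of 26 chemotaxis, 8 of 14 RuBisCO and Calvin cycle (1 rose) and 4 of 4 b561 locus genes fell (fixed lists 13 and 10 adjusted over the list alone), camera adjusted p = 4.3e-06, 0.00644 and 0.0127, or 0.0599 to 0.64 with estimated correlation. In all 693 genes differed by edgeR, 299 higher and 394 lower at 90 min, 216 at least 2-fold. The count was 312 without 90 min replicate 1, 415 without 35 min replicate 1, 437 after thinning and 131 in the own-group model.

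The FeCl2 responses were compared with each other across the 2936 genes. At all 3 times, 1136 genes were called in 1 direction, 632 higher and 504 lower, where independent lists would share 66.9 and 69.0. Called at only 15, 35 or 90 min were 127, 165 and 276 genes, and in opposite directions 22. In 20 simulations, unchanged groups against the same controls gave 0 shared genes by edgeR. With no effect to call, this does not size what shared controls add. The 3 controls were not split, so part of the excess is open to them. The pairs of times shared 724 higher and 663 lower genes (15 and 35 min), 667 and 594 (15 and 90 min) and 674 and 590 (35 and 90 min).

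The FeCl2 response was set against the donor effects in 9 correlations (3 times, 3 stages) across genes, which are not independent replicates. With the donor effect at mid-log, which shares no library with it, Pearson's r was 0.355 at 15 min, 0.379 at 35 min and 0.405 at 90 min. At 90 min Spearman's rho was 0.458. There 399 genes were higher and 420 lower in both, against 202 and 229 for independent lists, with 166 opposite. With late-log the values were 0.330 and 0.384, with 246 and 334 shared genes against 149 and 171, and 139 opposite. With stationary phase, which shares its control libraries, they were 0.569 and 0.643 (0.512 and 0.484 simulated with no effect). At 15 and 35 min, r was 0.306 and 0.299 with late-log, and 0.515 and 0.517 with stationary phase (simulated 0.511 and 0.469). Covariances there were 0.709, 0.787 and 0.831 at the 3 times (simulated 0.0562, 0.0582 and 0.0568). Simulated r is noise alone, so it is not comparable. At 90 min 510 genes were higher and 560 lower in both (221 and 247 for independent lists) and 73 opposite.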

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

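The tests of abundant genes, of handling and of other splits of the libraries were set before their results were seen; the other tests here were chosen only after the results were seen. Differences between groups were found for 121 interaction terms at late-log and 345 in stationary phase, for 106 genes between 15 and 35 min, and for 693 genes between 35 and 90 min. The part of the table's larger total that lay in no gene averaged 5.19%, 4.14% and 4.48% in mid-log, late-log and stationary thiosulfate libraries, above the 2.1%, 2.56% and 2.9% in Fe(II)-citrate libraries; what the larger total counts is not stated in the sources used here, so whether these are unassigned reads stays open.

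Of 100 splits of the libraries per interaction, the real one gave most terms, 121 and 345, and the next 59 and 182. Splits also mixed stages, so they cannot single out the interaction. For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real and highest other counts were 1502 and 0, 1118 and 2, and 1635 and 1 between donors, and 1649 and 0, 1690 and 3, and 1681 and 13 after FeCl2. They were 23 and 6, and 446 and 4 between stages on Fe(II)-citrate, 108 and 11, and 10 and 0 on thiosulfate, and 106 and 12, and 693 and 339 between times.

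The response within 15 min of FeCl2 covered 1649 genes. No few genes took most counts: the 20 most abundant held 10.4 to 19.3% per library. Without them 1653 genes were called, 726 higher and 927 lower against 822 and 827. A return to mid-log was argued against: stationary and mid-log thiosulfate differed by 10 genes, so the 86.2% called alike against both was no test. Handling stays open: r with the mid-log donor effect was 0.355 across genes, but without a mock addition handling cannot be told from Fe(II).

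In late-log thiosulfate replicate 3, 14 genes stood over 4-fold above both other replicates, among them the mto genes Slit_2496 to Slit_2498 and the rubrerythrin region. RNA of another culture of the series mixed in was argued against, as 64.3% of the set lay over 1.5 times above the highest library of any other group. RNA of an FeCl2 culture was argued against too: the median rise of the complex III genes was -0.0137 of the rise that the share needed for the mto genes would give. No biological explanation was tested. Mid-log Fe(II)-citrate replicate 2 had 20 genes over 4-fold above both others; it was left out only by itself, which gave 1277 genes between donors at mid-log.

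Stationary and mid-log cultures differed by 446 genes on Fe(II)-citrate and 10 on thiosulfate. The shallow stationary thiosulfate library did not account for it, as thinning left 300 and 6 genes. Nor did 1 library, since the lowest count was 199, without stationary Fe(II)-citrate replicate 3. The spread shared by all groups stays open, as own-group models gave 373 and 160 genes, 2.33 times as many on Fe(II)-citrate. On thiosulfate the count was 0 by edgeR without stationary replicate 3, with 257 genes at an unadjusted p under 0.05, and DESeq2 with all libraries gave 22. A smaller change between stages on thiosulfate stays open as a hypothesis.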

How the results depend on the processing

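The block of 2 groups, the shallow libraries, the 4 libraries standing apart and the abundant genes were alternatives chosen after seeing the data, the last before its own result was seen. Counts between donors and after against before FeCl2 stayed within 1.5 times under every alternative run. Sharing between the 3 times did so under the only 1 run. Of 302 pairs of a gene and a comparison in the text, 212 were past the threshold, 157 under every alternative run, and 43 changed sign under some alternative. Of 102 calls of fixed lists, 5 stayed with estimated correlation, 103 were made with RLE and 101 with the block; leaving out 1 library gave 94 to 105. Of 178 calls of all lists, 51 ended without at least 1 library, and of those only cyc2, mto, PCC3 and sulfur oxidation loci are described. With no filter, the correlations of the 90 min response with the donor effects, 0.330 at late-log and 0.569 in stationary phase, became 0.325 and 0.574, beyond their spread between replicates. Removing structural RNA was not run, as none was found. Simulated recovery, given above, holds for these depths, spread and replicates. Depth was not varied alone.

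Counts that moved by over 1.5 times are given next, and the cause was not tested. From mid-log to late-log on Fe(II)-citrate, 23 genes became 15 with the replicate block, 65 with DESeq2, 57 in the own-group model, 244 with the block in it, and 0 to 71 with 1 library left out; beside the 0, edgeR had 210 to 289 genes at an unadjusted p under 0.05. From mid-log to stationary phase on Fe(II)-citrate, 446 became 199 to 480 with 1 library left out. On thiosulfate, 108 at late-log became 57 to 129 with 1 library left out, and 10 in stationary phase became 6 after thinning, 22 with DESeq2, 160 in the own-group model, 6 without both shallow libraries and 0 to 6 with 1 library left out. The late-log interaction of 121 terms became 234 in the own-group model, 57 without both shallow libraries, 190 without 4 libraries standing apart and 35 to 159 with 1 left out. The stationary interaction of 345 became 223 after thinning and 215 to 399 with 1 left out. Between 15 and 35 min, 106 became 59 after thinning and 52 to 107 with 1 left out. Between 35 and 90 min, 693 became 437 after thinning, 131 in the own-group model and 312 to 909 with 1 left out.

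Log2 fold changes that changed sign are given by comparison with the setting in parentheses, as the range over libraries where 1 was left out; the cause was not tested. Between donors at mid-log, Slit_2495 was 0.046 (RLE), 0.059 (DESeq2) and -0.27 to 0.18 (1 left out) and Slit_2496 was -0.14 (thinned). Between donors at late-log, Slit_0263 was 0.11 (4 left out) and -0.22 to 0.11 (1 left out), Slit_2497 was 0.60 (4 left out) and -4.53 to 0.59 (1 left out) and Slit_2498 was 2.60 (4 left out) and -4.48 to 2.59 (1 left out). Between donors in stationary phase, Slit_2495 was 0.17 (4 left out) and -0.82 to 0.43 (1 left out), Slit_2497 was 0.30 (thinned), 0.043 (4 left out) and -1.08 to 0.62 (1 left out) and Slit_2498 was -0.46 (thinned) and -1.38 to 3.22 (1 left out). At 15 min, Slit_2495 was 0.28 (thinned) and -0.62 to 0.63 (1 left out). At 35 min, Slit_2498 was -4.88 to 1.34 (1 left out). At 90 min, Slit_0870 was 0.49 (thinned). Late-log against mid-log on Fe(II)-citrate, Slit_0868 was 0.079 (thinned) and -0.31 to 0.23 (1 left out), Slit_0869 was -0.15 to 0.18 (1 left out) and Slit_2495 was -0.24 to 0.14 (1 left out). There, Slit_2496 was 0.046 (thinned). Stationary against mid-log on Fe(II)-citrate, Slit_0263 was -7.9e-06 (block), -0.51 (4 left out) and -0.50 to 0.31 (1 left out), Slit_0867 was -0.061 (thinned) and Slit_0868 was -0.51 to 0.032 (1 left out). There, Slit_0870 was 0.46 (4 left out) and -0.75 to 0.46 (1 left out). Late-log against mid-log on thiosulfate, Slit_0263 was -0.24 to 0.048 (1 left out), Slit_0868 was -0.12 (4 left out) and -0.11 to 0.80 (1 left out) and Slit_0869 was 0.025 (DESeq2) and -0.18 to 0.15 (1 left out). There, Slit_0870 was -0.44 (4 left out) and -0.42 to 0.58 (1 left out) and Slit_2498 was -2.07 (4 left out) and -2.06 to 4.98 (1 left out). Stationary against mid-log on thiosulfate, Slit_0263 was 0.029 (RLE), 0.0088 (block), 0.029 (DESeq2) and -0.10 to 0.079 (1 left out), Slit_0867 was 0.0031 (RLE), 0.015 (thinned), 0.028 (own groups), 0.12 (shallow left out) and -0.19 to 0.12 (1 left out) and Slit_0869 was -0.016 (thinned) and -0.053 to 0.21 (1 left out). There, Slit_0870 was 0.0038 (own groups), 0.056 (shallow left out) and -0.20 to 0.054 (1 left out), Slit_2496 was 0.012 (RLE), 0.093 (block), 0.088 (DESeq2) and -0.20 to 0.16 (1 left out) and Slit_2498 was 0.071 (thinned) and -3.29 to 0.28 (1 left out). In the late-log interaction, Slit_0868 was 0.063 (4 left out) and -0.85 to 0.051 (1 left out), Slit_0869 was -0.0050 (DESeq2) and -0.12 to 0.25 (1 left out) and Slit_0870 was -0.25 to 0.74 (1 left out). There, Slit_2498 was 1.36 (4 left out) and -5.68 to 1.36 (1 left out). In the stationary interaction, Slit_0263 was -0.0088 (block), -0.51 (4 left out) and -0.50 to 0.32 (1 left out), Slit_0867 was -0.076 (thinned) and Slit_0870 was 0.019 (block), 0.38 (thinned), 0.10 (DESeq2), 0.48 (4 left out) and -0.71 to 0.49 (1 left out). There, Slit_2495 was 0.20 (4 left out) and -0.76 to 0.49 (1 left out) and Slit_2498 was 0.094 (4 left out) and -2.58 to 2.02 (1 left out). At 35 against 15 min, Slit_0263 was -0.23 (4 left out) and -0.23 to 0.44 (1 left out) and Slit_0867 was 0.13 (thinned). At 90 against 35 min, Slit_0263 was 0.047 (own groups), 0.27 (4 left out) and -0.23 to 0.31 (1 left out) and Slit_0867 was 0.010 (own groups) and -0.39 to 0.13 (1 left out).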

Other observations

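Several lists were not called by camera in any comparison, although members moved both ways. Of the iron uptake and TonB system genes at mid-log, 1 rose and 5 fell of 18 (1 and 5 adjusted over the list alone), and at 90 min after FeCl2 3 rose and 4 fell of 18 (3 and 4 adjusted over the list alone). Of the genes for iron-sulfur cluster assembly and binding at 15 min after FeCl2, 1 rose and 6 fell of 10 (1 and 6 adjusted over the list alone), and of the TCA cycle genes 1 rose and 9 fell of 17 (2 and 9 adjusted over the list alone). Of the oxidative stress genes found by whole words, at 90 min 4 rose and 10 fell of 25 (4 and 10 adjusted over the list alone). Of the nitrogen fixation and assimilation genes, with 2 for hydrogenase, in stationary phase between donors, 5 rose and 7 fell of 24 (5 and 7 adjusted over the list alone). Of the polysaccharide genes at 15 min, 2 rose and 1 fell of 6 (2 and 1 adjusted over the list alone).

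The following tests were chosen only after the results were seen. Whether Fe(II) itself raised Slit_1031 to Slit_1035, high on Fe(II)-citrate at every stage, stays open. At 90 min after FeCl2 their median was -0.33 (1 of 5 called, largest standard error 0.55), but those cells had grown on thiosulfate. The hypothesis that complex III transcripts reached only the level of Fe(II)-grown cells was argued against by a median of 3.11 at 15 min over mid-log Fe(II)-citrate, with 7 of 7 genes called. For mto transcripts at 90 min it was argued against by a median of 4.32 over mid-log Fe(II)-citrate, with all 4 genes called. These values may reflect a response to sudden Fe(II), but the missing mock addition leaves handling open.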
